A study of Equus caballus with 64 samples.

How the data were processed

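Whole venous blood of 32 Welsh Pony foals was collected 30 and 95 days after weaning in RNA-stabilising tubes, per the labels' protocols. Total RNA was extracted with a blood RNA kit and labelled with Cy3 for one-colour Agilent arrays. Scanned images were quantified with Agilent Feature Extraction 10.10.1.1, per the submitters' processing notes. Background correction, normalization, choice of features and scaling of the table are not given in the sources used here. Array slide and scan day are not given either, so they were not tested as batches.

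The deposited values are scores: their unit is not stated, and they are not plain log2 intensities, since they run from 1.49 to 230.8. Each feature's residual SD was computed with the number of arrays less 1 as divisor. Under a model of weaning by day plus sex it stopped at 1.0003, with 0 of 26534 features above 1.01. It reached 2.13 under weaning by day alone and 1.13 under weaning plus day plus sex. Of the 59 residual components of that model, 4 were nearly empty, holding at most 0.286% of the variance each against a median of 1.11%. The values therefore behave as if each feature had been divided by its residual SD from that model and shared variation had then been subtracted. This is an inference from the values, and the steps that were taken are not given in the sources used here. Such a step would make the spread between arrays too small and p-values too low, and it rules out fold changes. A feature's mean is then not its brightness, and no signal over background was used here.

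The tests had been chosen before the data were examined on the assumption of log2 values; they were kept and run on the values as deposited. Samples were grouped by the weaning type, day, foal and sex in the labels, and each table column was matched to its sample, with 0 columns unused. All fits used limma 3.58.1 in R 4.3.3 with empirical Bayes moderation. Weaning was tested on the 4 group means with the foal as a random block, at a consensus correlation of 0.267. Change between days was tested with the foal as a fixed block and a day term per weaning type, or per sex and weaning type. Sex and its interaction with weaning were tested on the means of weaning by day by sex with the foal as a random block, at a correlation of 0.272. All tests were two-sided, and features at a Benjamini-Hochberg adjusted p under 0.05 over all 26534 features were called, separately for each of the 10 comparisons. Confidence intervals are at 95%.

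Arrays were paired by foal, since the labels give the same foal on both days. The deviations of a foal's 2 arrays from their group means correlated at 0.274 on average, from -0.115 to 0.487, and at over 0.1 in 31 of 32 foals. Between different foals the mean was -0.00892, but the range, from -0.487 to 0.431, overlapped. The best match on the other day was the same foal for 25 of 32 day 30 arrays and 23 of 32 day 95 arrays.

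The rule for named genes needs gene symbols, which the files do not give. In its place, at most 2 features in each direction were taken for each comparison. For the change between days these were the largest changes among called features moving that way in at least 24 of 32 foals. Elsewhere they had the smallest p. This shortened rule was set after the table had been seen. The 25 gene lists fixed beforehand, their tests, covariates for blood cell composition and the choice among probes of a gene all need gene names and were not run.

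Each kind of fit was tested on simulated data with 200 of 26534 features changed by 0.5, 1 or 1.5 units. Simulated features varied independently of each other, with spreads estimated from the deposited values. Alternatives were quantile normalization, subtraction of each array's 75th percentile, features with a mean above the median feature, sex or sex by time as a covariate, no block, only the arrays of the groups compared, array weights, trended and robust moderation, an adjusted p of 0.10, and each foal left out in turn. The filter on the mean was kept as chosen although it does not select bright features here. Quantile normalization and the 75th percentile were kept too. If each feature was divided by its own SD, they change scores and do not equalise intensities between arrays. Fits with fewer residual degrees of freedom, fits without the foal with an outlying array, and leaving out each foal for the sex comparisons were added after seeing the data. An array was outlying when its root-mean-square deviation from the group means exceeded the upper quartile by 1.5 times the interquartile range. For each comparison, 100 splits including the real one were drawn by reassigning weaning type or sex among foals or swapping days within foals, with the correlation between days held at its value. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.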

Results

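Gene expression was measured in the whole venous blood of 32 Welsh Pony foals, 16 of which underwent what the submitters call brutal weaning and 16 progressive weaning. Each weaning type held 9 females and 7 males. Every foal was bled 30 and 95 days after weaning into tubes that stabilise RNA, and each sample was hybridised to a one-colour Agilent array with Cy3 label. The 64 arrays form 4 groups of 16. The deposited table holds 26534 array features with 0 missing values. It identifies each feature only by its number on the array, and the files do not pair these numbers with gene names. No gene is therefore named, and at most 2 features that were higher and 2 that were lower are given for each comparison.

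The deposited values are scores without a stated unit, from 1.49 to 230.8, with array medians between 26.3 and 26.6. After removal of weaning by day and sex, the largest standard deviation (SD) of any feature was 1.0003, with a median of 0.705, so differences are given in score units and not as fold changes. The number of arrays limits the precision: the median 95% confidence interval reached 0.513 units either side of a weaning difference on a single day, and 0.297 units either side of the change between days over all foals. Of the 2016 pairs of arrays, 0 held identical values, and the highest correlation between the deviations of any pair from the feature means was 0.464.

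The study was concerned with how progressive weaning affects the behaviour and physiology of foals. At day 30, blood of the brutal and progressive foals differed at 1 of 26534 features. Feature 23962 had a mean of 47.3 ± 1.08 (SD, n = 16) in brutal foals and 49.4 ± 0.847 (SD, n = 16) in progressive foals. The difference, brutal minus progressive, was -2.10 ± 0.370 (standard error, SE), with a limma adjusted p of 0.00853. All 16 progressive foals lay above the brutal mean, and all 16 brutal foals lay below the progressive mean. After quantile normalization the difference was -1.92 with an adjusted p of 0.0589, no longer past the threshold. It was 0.031 with the 75th percentile subtracted and 0.0055 without the foal as a block, and it ranged from 0.00102 to 0.0353 with each of the 32 foals left out in turn. When weaning type was reassigned among the foals, 10 of 100 splits, the real one included, called at least 1 feature. At day 95 the same feature had means of 46.5 ± 1.26 (SD, n = 16) and 47.2 ± 1.02 (SD, n = 16).

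**Figure D1:**
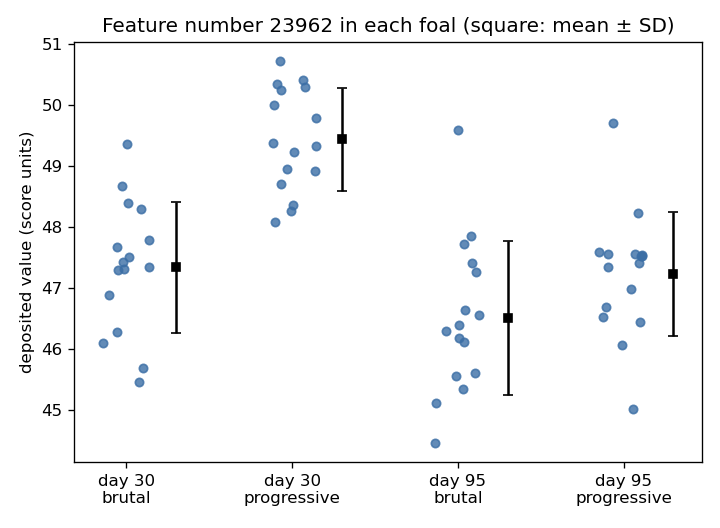
Deposited value of feature 23962 (score units, vertical axis) in each foal, by day and weaning type (horizontal axis); points are foals and squares with bars are the group mean ± SD, n = 16. At day 30 the progressive foals lie between 48.1 and 50.7 and the brutal foals between 45.4 and 49.4.

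The next feature lower in brutal foals at day 30 was 8301, with means of 17.1 ± 0.537 and 17.9 ± 0.354 (SD, n = 16 each) and an adjusted p of 0.373, which did not pass. The features with the smallest p among those higher in brutal foals were 22861 and 36840, with differences of 0.802 ± 0.215 and 0.704 ± 0.190 (SE), both at an adjusted p of 0.721. At an unadjusted p under 0.05, 1487 features differed, and 2151 with the 75th percentile subtracted; the 99 reassignments of weaning type gave between 532 and 4064. In simulated data with the same design, limma recovered 51% of changes of 1 unit and 94% of changes of 1.5 units at day 30. The simulated features varied independently and took their spread, which may be too small, from the deposited values. Each run also changed 200 features, and the adjusted threshold is stricter when fewer features change. These rates may therefore be too high for the real data, above all if only few features changed.

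At day 95, limma called 0 of 26534 features between weaning types, and 474 had an unadjusted p under 0.05. The features closest to the threshold were 9185 and 5343 among those higher in brutal foals, with differences of 1.03 ± 0.265 and 1.04 ± 0.283 (SE). Among those lower they were 26689 and 41998, with differences of -1.21 ± 0.296 and -1.22 ± 0.342 (SE). The adjusted p of these 4 features rounded to 1. The 95% confidence interval of the weaning difference lay within 1 unit of 0 for 92.7% of features at day 95 and for 87.1% at day 30. A difference of 1 unit exceeds the median residual SD of 0.705 and about equals the largest, 1.0003. Here and below, such intervals thus still allow differences larger than a typical feature's spread. They are also too narrow if the spread between arrays was made too small. Simulated changes of 1 unit at day 95 were recovered in 52.5% of cases and those of 1.5 units in 96.5%. These rates may be too high for the same reasons as at day 30.

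Averaged over both days, limma called 0 features between weaning types, with 935 at an unadjusted p under 0.05 and a smallest adjusted p of 0.248. The fit without the foal as a block called 1 feature. The interval lay within 1 unit of 0 for 98.0% of features.

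More features were called between the days than between weaning types or between the sexes. The change between days was tested within foals, with a median SE of 0.146 units. For weaning and sex over both days, tested between foals, the median SE was 0.204 and 0.203 units, so the counts also reflect precision. Over all 32 foals, 8800 features (33.2%) changed between day 30 and day 95, of which 3914 were higher and 4886 lower at day 95. Among the features that moved the same way in at least 24 foals, feature 14023 rose most, by 2.14 ± 0.147 units (SE, adjusted p = 2.84e-12), and was higher at day 95 in 32 of 32 foals. Its mean went from 30.0 ± 0.829 to 32.1 ± 0.783 (SD, n = 16) in brutal foals and from 29.8 ± 1.02 to 31.9 ± 0.708 (SD, n = 16) in progressive foals. Feature 6188 rose by 2.10 ± 0.170 units (SE, adjusted p = 2.99e-11), also in 32 of 32 foals. Feature 5369 fell most, with a change of -1.55 ± 0.194 units (SE, adjusted p = 1.31e-07) and lower values at day 95 in 29 of 32 foals. Feature 23962 changed by -1.52 ± 0.233 units (SE, adjusted p = 4.51e-06) and was lower in 27 of 32 foals. This averages unlike changes: its mean went from 47.3 to 46.5 in brutal foals and from 49.4 to 47.2 in progressive foals. The difference between these changes did not pass as an interaction of day and weaning type.

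The median size of the change among the 8800 features was 0.534 units, and 817 changed by over 1 unit. The balance of directions depended on the scaling: with the 75th percentile of each array subtracted, 4876 features were higher and 3250 lower at day 95, and the median change of all features moved from -0.0595 to 0.0207. If each feature was divided by its own SD, subtracting the same score is a different step in intensity for each feature. Neither balance need then hold for expression. The direction of the 4 named features was the same under both scalings.

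Taken separately, 4096 features changed in brutal foals (2095 higher, 2001 lower) and 4996 in progressive foals (2466 higher, 2530 lower). Subtracting the 75th percentile turned the progressive split to 3445 higher and 1164 lower. Without pairing the arrays by foal, the counts were 1566 in brutal and 2315 in progressive foals. The 2 weaning types share no foal, and their estimates correlated across features at r = 0.773 (Spearman's rho 0.712); features are not independent replicates. When the days were swapped in randomly chosen foals, 100 draws gave r between -0.386 and 0.334. Swapped days are comparable with the real ones only if the values were not adjusted under a model holding the real days. Of the called features, 1561 were higher in both types, where independent lists would share 195, and 1066 were lower in both, where independent lists would share 191. Only 1 feature was called in opposite directions. An adjustment or a batch of arrays that follows the day would be shared by both types. Neither r nor the shared calls can tell it from a change in the foals.

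**Figure D2:**
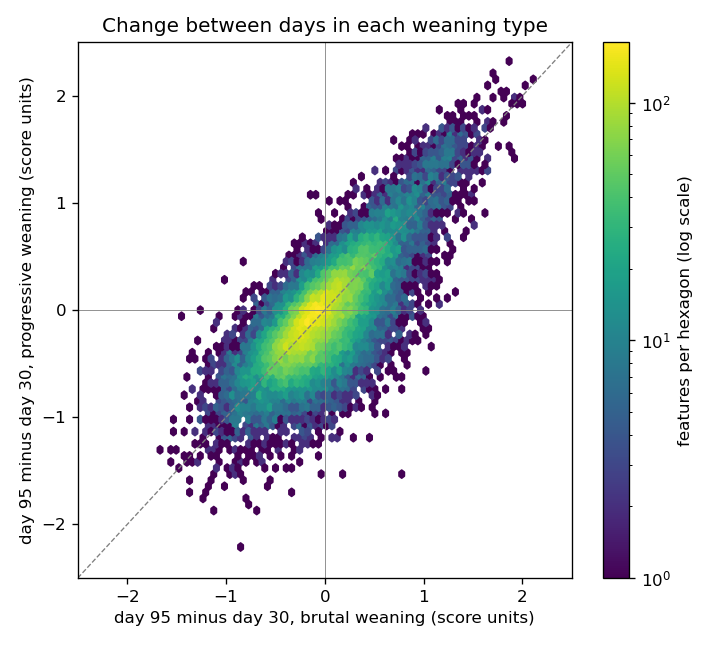
Change between day 30 and day 95 (score units) of all 26534 features in brutal foals (horizontal axis) and progressive foals (vertical axis); colour gives the number of features per hexagon on a log scale and the dashed line marks equal change. The estimates rise together across features, with r = 0.773.

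The difference between weaning types in this change was tested directly. Limma called 0 features for the interaction of day and weaning type, with 977 at an unadjusted p under 0.05 and a smallest adjusted p of 0.514. The median interval reached 0.594 units either side, and it lay within 1 unit of 0 for 74.7% of features. Simulated interactions of 1 unit were recovered in 38% of cases and those of 1.5 units in 77%, rates that may be too high for the reasons given for day 30.

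Sex was compared because the labels give it for every foal. Over both days, 505 features differed between the 14 males and 18 females, of which 306 were higher and 199 lower in males. Feature 39174 had a mean of 22.8 ± 1.498 over 28 male arrays and 19.1 ± 0.482 over 36 female arrays, a difference of 3.80 ± 0.243 units (SE, adjusted p = 7.31e-19). Feature 25944 was higher in males by 3.27 ± 0.212 units (SE, adjusted p = 7.31e-19), and its lowest male array, at 15.7, lay above its highest female array, at 15.3. It was the only feature without overlap. Features 50323 and 33435 were lower in males, by differences of -2.46 ± 0.248 and -1.23 ± 0.139 units (SE), with adjusted p of 5.59e-11 and 2.98e-09. Without the foal as a block the count was 1365, but that fit treats the 2 arrays of a foal as 2 foals and overstates the evidence. With residual degrees of freedom lowered for the nearly empty components of the table it was 294, a step that does not restore variation that may have been subtracted. Among features with a mean above the median feature only, the count was 85 (63 higher, 22 lower in males). With single foals left out it ranged from 279 (without brutal replicate 13) to 624.

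The change between days differed between the sexes at 900 features, 461 with a more positive change in males and 439 with a more positive change in females. Feature 61238 changed by 0.802 ± 0.595 units in males (SD over 14 foals) and by -0.678 ± 0.596 in females (SD over 18 foals), rising in 13 of 14 males and in 3 of 18 females. The difference in change was 1.48 ± 0.225 units (SE). Feature 6969 rose in 13 of 14 males and in 2 of 18 females, with a difference of 1.64 ± 0.252 units (SE). Feature 23871 went the other way, rising in 2 of 14 males and in 17 of 18 females, with a difference of -1.43 ± 0.214 units (SE). Feature 7263 rose in 4 of 14 males and in 18 of 18 females, with a difference of -1.40 ± 0.216 units (SE). The limma adjusted p of all 4 was 0.00118. Without pairing by foal, the count fell to 61, and features 61238 and 6969 had adjusted p of 0.0501 and 0.0547. With residual degrees of freedom lowered as above, 385 features were called.

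**Figure D3:**
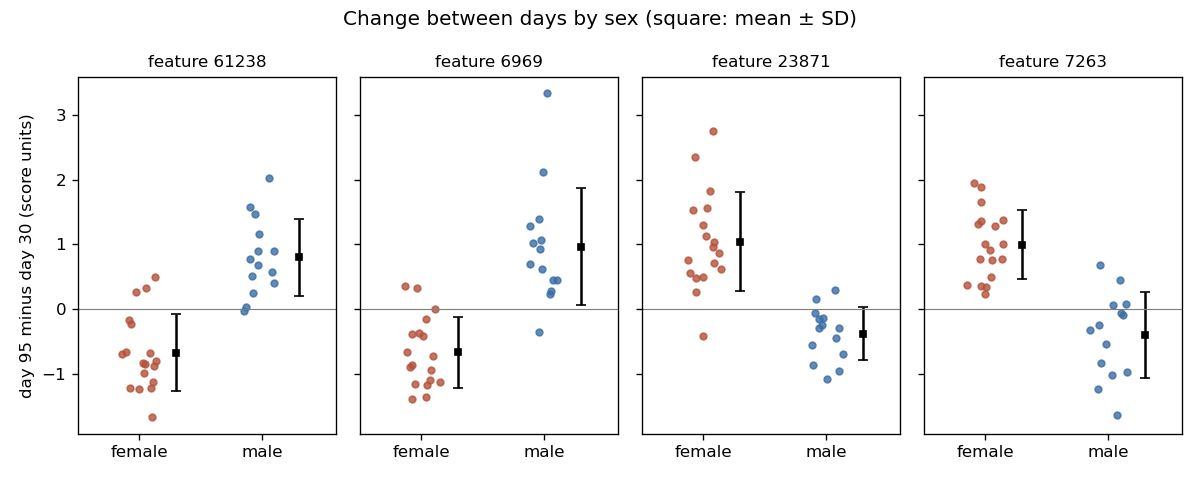
Change between day 30 and day 95 (score units, vertical axis) in 18 female and 14 male foals for the 4 features with the smallest p for a sex difference in change; points are foals and squares with bars are the mean ± SD. Features 61238 and 6969 rose in 13 of 14 males each, and feature 7263 rose in 18 of 18 females.

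Among the 900 features, the change itself passed the test in males for 605, in females for 381 and in both sexes for 104. The estimates had opposite signs in males and females for 673, which is favoured by choosing features on the difference and is not a count of features that changed both ways. Within a single weaning type, the sex difference in change was called at 6 features in brutal and 292 in progressive foals; whether it differed between the types was not tested. Over the 900 features, the median size of the sex difference was 0.268 units at day 30 and 0.786 units at day 95. These features were chosen on the change of the sex difference between the days, so both values are affected by that choice. Tested one day at a time over all features, 38 differed between the sexes at day 30 and 1761 at day 95. The interaction of weaning type and sex gave 0 calls in limma, with 1025 features at an unadjusted p under 0.05. Its median interval reached 0.811 units either side, and the interval lay within 1 unit of 0 for only 41.8% of features. This comparison was not simulated.

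**Figure D4:**
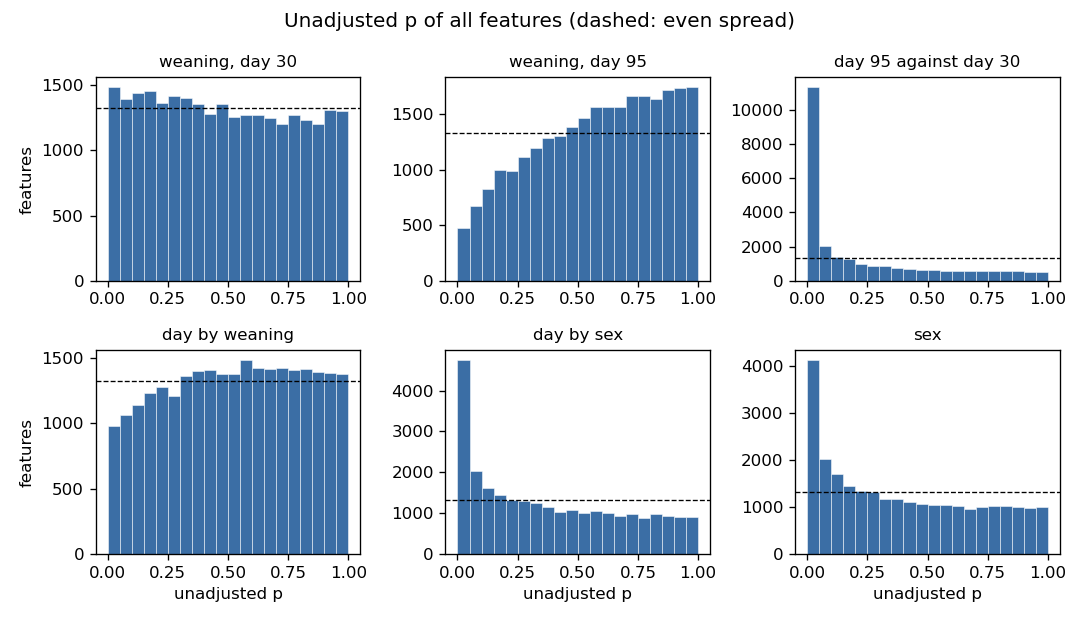
Number of features (vertical axis) by unadjusted p (horizontal axis) for 6 comparisons; each bar spans 0.05 and the dashed line marks an even spread. The bar nearest 0 holds 11353 features for the change between days and 474 for weaning at day 95.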

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

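Of the tests here, the comparison of weaning types against reassigned sexes was chosen after the observed correlation had been seen, and the fits without a foal and with fewer degrees of freedom were added after seeing the data. The change between days differed between males and females at 900 features, tested as an interaction. The features named for it had differences in change, male minus female, of 1.48 units for 61238, 1.64 for 6969, -1.43 for 23871 and -1.40 for 7263.

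Of 100 reassignments of sex within weaning types, 1, the real one, called as many, and the highest other called 24. Chance can be excluded for the count only if the values were not adjusted in a way that treats the real sexes apart from reassigned ones, which stays open. Position on the array is argued against by a correlation of 0.00981 between the test statistics of consecutive feature numbers. The estimates of the weaning types, which share no foal, correlated at r = 0.335; 2 of 100 reassignments, the real one included, reached that value, with a highest other of 0.345. Under the same condition, this argues against single foals rather than sex as the whole source. The calls were uneven between the types, with 6 features in brutal and 292 in progressive foals, and that difference was not tested. Without progressive replicate 12, the foal with an outlying array, the number of called features was 78.4% of that with it, and 661 of the 900 were still called, which argues against that foal as the whole source. Lowering the residual degrees of freedom, which can only reduce a count, gave 385 and does not bear on where the pattern comes from. An adjustment of the values before deposit, a sex difference in development between the days, and a batch that follows day and sex stay open and were not tested.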

How the results depend on the processing

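Fits with lowered degrees of freedom, without the foal with an outlying array, and with single foals left out for the sex comparisons were chosen after seeing the data. Weaning at day 95, the interaction of day and weaning, and the interaction of weaning and sex had 0 calls under every alternative run. Quantile normalization left 0 features for weaning at day 30. Restriction to features with a mean above the median feature tests fewer features. It gave 1832 for time in brutal foals, 2341 in progressive foals, 4106 over all foals, 364 for time by sex and 85 for sex. Each of these counts fell by more than the share of features left out, the count for sex most of all. The cause was not tested. With no replicate block the counts were 1566, 2315 and 6287 for time in brutal, progressive and all foals, 61 for time by sex, 1365 for sex and 1 for weaning over both days; the block changed no other call count by over 1.5 times. An adjusted p of 0.10 gave 1778 for time by sex and 1020 for sex, through its looser threshold. Lowered degrees of freedom, which can only cut counts, gave 385 for time by sex and 294 for sex. For time in brutal, progressive and all foals they gave 2875, 3662 and 7589. These fits do not restore variation that may have been subtracted, so they cannot show whether p-values are too low. Without the block, the tests of sex and of weaning over both days treat a foal's 2 arrays as 2 foals. Their counts of 1365 and 1 thus overstate the evidence. For the other changes the cause was not tested. With each foal left out in turn, weaning at day 30 gave 1 to 2 features (2 without brutal replicate 8), and feature 23962 was called in all 32 fits, with adjusted p from 0.00102 to 0.0353. Weaning over both days gave 0 to 1 (1 without brutal replicate 14). Sex gave 279 to 624, with 279 without brutal replicate 13, 306 without brutal replicate 15 and 319 without progressive replicate 8. Time over all foals gave 8215 to 8923, and time by sex 659 to 1299. Quantile normalization called 8648 features for time over all foals, of which 7793 were among the 8800. Gene lists, cell composition covariates and probes per gene were not run, since they need gene names. Signal over background was not used here, so its limits are unknown.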

Other observations

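The tests of the authors' adjustment and of array position for the change between days, and of the spread of the day 30 arrays, were chosen after the result had been seen.

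For the change between days over all foals, 1 of 100 splits that swapped days within foals, the real one, called as many as 8800 features, and the highest other called 1123. For brutal foals it was 1 of 100, with 4096 against a highest other of 2, and for progressive foals 1 of 100, with 4996 against 1. Chance can be excluded for these counts only if the values were not adjusted under a model holding the real days, since swapped days would otherwise not be comparable with the real ones. Whether such an adjustment contributed could not be decided: 3.68% of features had an unadjusted p under 0.05 for the interaction with weaning, a term of the same model, within the range of 2.17% to 9.47% over reassigned weaning types. It stays open. Test statistics of consecutive feature numbers correlated at 0.00111, which argues against position on the array. Age, season and array batches that follow the day stay open and were not tested.

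For weaning at day 30, 10 of 100 reassignments of weaning type among foals, the real one included, called at least 1 feature, and the highest other called 299, so chance cannot be excluded. Weaning at day 95, weaning over both days and the interactions of weaning with day and with sex had 0 calls, which each of the 100 splits reaches by construction (100 of 100), so the splits say nothing about chance there. Their highest other counts were 7, 248, 1 and 284. Splits that called 299, 248 or 284 features may reflect a structure among the foals or correlation between features; neither was tested. For sex, 1 of 100 splits, the real one, reached 505, against a highest other of 9. Chance can be excluded there only if the values were not adjusted under a model holding the real sexes, which stays open.

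Few features had a small p for weaning at day 95: 474 at an unadjusted p under 0.05, where evenly spread p-values would give 1327. One hypothesis was variation shared between features. Of 100 splits of the foals, 2, the real one included, gave as few, and the others ranged from 443 to 3196. If the values were adjusted under a model holding the real weaning types, reassigned types are not comparable with them, so the hypothesis stays open.

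At day 30, arrays of progressive foals lay farther from their group mean than those of brutal foals, with root-mean-square deviations of 0.779 ± 0.145 and 0.673 ± 0.0795 units (SD, n = 16 each), and 12 of 16 progressive arrays above the brutal mean. The hypothesis that progressive foals vary more at day 30 gave a two-sided permutation p of 0.0138, or 0.0275 adjusted over the 2 days; at day 95 the difference was 0.00768 units with p = 0.829. Without progressive replicate 12, whose day 30 array reached 1.11, the day 30 difference was 0.0843 units in place of 0.106. That foal alone thus did not give all of the difference. The permutation p was then 0.0275 in place of 0.0138, both before adjustment over the 2 days. It is not comparable with the equal value of 0.0275 for all foals, which is already adjusted. The adjusted value without that foal was not computed. Raised by adjustment as the value for all foals was, from 0.0138 to 0.0275, it would no longer pass the adjusted threshold. The hypothesis is thus not shown to hold without that foal. Progressive replicates 13, 14, 15 and 16 reached 0.943, 0.880, 0.971 and 0.936, above the highest brutal array, at 0.840. The remaining 11 progressive arrays lay between 0.645 and 0.830, within the brutal range of 0.556 to 0.840. Replicates 14, 15 and 16 also had the highest medians of the 64 arrays, 26.54, 26.60 and 26.63. Much of the difference may come from these few arrays, but they were picked for lying highest, and the difference without them was not tested. Progressive replicates 12 to 16 were also the last progressive foals in the order of the samples. Whether that order follows slide or scan day is not known. The spread may differ between the types at day 30, but a batch of arrays stays open, since slide and scan day are not given, and the change of this difference between days was not tested.

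The arrays of brutal replicate 7 were the only pair from one foal to correlate below 0.1, at -0.115. Without this foal, 8849 features were called for the change between days over all foals and 870 for its interaction with sex.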
